A study of Mus musculus with 2 samples.

How the data were processed

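Liver of male C57BL6 mice aged 2 months was fixed in formaldehyde, and its chromatin was sheared by sonication before immunoprecipitation, per the labels' protocols. The labels describe 1 DNMT1 ChIP library and 1 input library, and 1 peak list of the ChIP against the input was used here. Whether both libraries came from the same animal, how many animals were used and which antibody was used are not given in the sources used here.

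Trimmomatic 0.38, BWA 0.7.17, SAMtools 1.9, Picard 2.18.12, MACS2 2.1.1.20160309, deepTools 3.3.0 and the mouse build mm10 are named in the submitters' processing notes, which state no order or settings. Narrow peaks were called on the ChIP library with the input library as control at a q-value cutoff of 0.05, in single-end mode, per the file headers. Tags were 74 bp long and were extended to fragments of 225 bp, and at most 1 tag was kept per position in each library, per the file headers. The larger library was scaled down to the smaller, the ranges named for the local background were 1000 and 10000 bp, and the effective genome size was 1870000000 bp, per the file headers. After duplicate removal the input held 1.48 times as many tags as the ChIP, so its background was divided by that ratio. With that division undone, the background was within 0.01 of a whole number of fragments at all 11 peaks with a pileup of at least 100. The same held at 1132 of the other 2162 peaks. Averages over 1000 or 10000 bp would seldom give whole numbers, so these ranges alone did not set the background.

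The pileup is a signal in fragments at the peak summit, in the unit of the ChIP library after duplicate removal, per the file headers. The fold enrichment is the authors' ratio of the summit pileup to the local background from the input, with a pseudocount of 1. The deposited −log10 p-value and −log10 q-value of each peak are the authors' Poisson test of the summit against that background and its Benjamini-Hochberg adjustment. Keeping 1 tag per position limits how high a pileup can rise, so the fold enrichment says little where both libraries are near that limit. The list holds only regions that passed the cutoff, so a gene without a peak is a gene without a called peak at this depth. Without replicates of the ChIP, p-values describe this list and not the variation between animals.

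From the peak list, each summit was assigned to a promoter (within 3000 bp of any annotated TSS), then exon, then intron, then intergenic sequence, using the GENCODE annotation for mouse release M21 and the GRCm38 genome, which shares its coordinates with mm10. Distances to a gene are to the nearest of its annotated TSSs, which can lie within the gene. Shares have 95% exact binomial (Clopper-Pearson) intervals. As a control, intervals of the same widths were placed at random on the same chromosomes outside assembly gaps 1000 times, and p was taken two-sided from the rank of the observed value. GC content, the ratio of observed to expected CpG and the repeat-masked share were computed over whole peaks, and over 500 bp to either side of the TSS for promoters. A promoter was called CpG-rich at a CpG ratio of at least 0.6. Peaks per Mb have exact Poisson intervals and exact binomial tests. Gene lists were compared by Fisher's exact test over 21911 protein-coding genes, and also with 10000 random lists matched on deciles of promoter CpG ratio. Binding words were compared between 200-bp windows at the summit and windows 2000 bp to each side by exact McNemar tests, with Benjamini-Hochberg adjustment over 11 words and both sides. A word was called when both sides passed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.

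The tests, the gene lists, the words, the alternatives first listed and the rule for named genes were fixed before the data were examined. The rule took the 10 peaks with the highest fold enrichment with their nearest TSS, each list gene with a peak within 3000 bp of a TSS or the 8 with the highest fold enrichment where a list had more, and 11 genes of the title or tissue with or without a peak. The genes of the title or tissue were Dnmt1, Yap1, Tead1, Tead2, Tead3, Tead4, Notch1, Notch2, Sox9, Hnf4a and Cebpa. Genes at peaks with a pileup of at least 100, Usp29 and Cdkn1c were named after their values were seen, and 1 gene that the rule takes is not reported here. The lists covered hepatocyte, biliary, endothelial, stellate cell and fibroblast, immune and erythroid markers, Notch, YAP/TEAD and Hippo, DNA methylation, imprinted, tumour suppressor, cholangiocarcinoma oncogene, Hox, ribosomal protein, histone, olfactory receptor, Zfp-numbered zinc finger, cell cycle, and immediate early and stress genes. The imprinted list had 54 symbols, of which 46 are annotated as protein-coding and entered the test.

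The procedures were tested on simulated data. Peaks placed at random gave a promoter p under 0.05 in 0 of 20 sets. With peaks planted at 15 of the 30 biliary genes, that list was called in 20 of 20 sets, and smaller effects were not simulated. With genes marked at random one by one, 2 of 380 list tests were called. With peaks set at the starts of random genes, 9 of 380 were called, 5 of them for histone genes and 3 for olfactory receptor genes, which lie in clusters whose members share peaks. The ETS word planted in 100 of 1000 windows was called in 20 of 20 sets, and 0 of 60 tests were called in random sequence. Summit and flank windows had the same base composition in these simulations, unlike the real windows. They therefore say nothing about words called through a difference in composition, and lower planted shares were not simulated. A doubled rate on chromosome 11 was called in 20 of 20 sets, and 0 of 420 tests were called on even chromosomes.

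Alternatives were stricter peak sets (fold enrichment at or above the median, −log10 q of at least 5, chromosomes 1 to 19 and X alone), promoter windows of 1000 and 10000 bp, protein-coding genes alone, overlap of the whole interval, gene bodies, windows of 500 bp and CpG-matched lists. Leaving out peaks with a pileup of at least 100, rearranged words, and imprinted genes that share a peak counted once were added after the data were seen.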

Results

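DNMT1, the methyltransferase that copies CpG methylation onto newly made DNA strands, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in liver of male C57BL6 mice aged 2 months. There was 1 DNMT1 ChIP library and 1 input library, which is sheared and sequenced chromatin DNA that was not immunoprecipitated. No value below therefore has a replicate check, the intervals cover counting error only, and each test describes this pair of libraries. The peak caller's header gave 40881288 tags for the DNMT1 ChIP, of which 20901534 were kept and 48.9% were removed as duplicates. For the input it gave 31922077 tags, of which 31012240 were kept and 2.85% were removed. The series title links DNMT1 to NOTCH and YAP1/TEAD signalling in the conversion of liver cells to a bile duct tumour, while the sample labels name liver alone and do not say whether it held tumours. The series design text also speaks of DNMT1 'retreatment', which the labels do not explain.

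The first comparison asked where DNMT1 signal exceeded the input. The authors called 2173 peaks with a median width of 283 bp (interquartile range 244 to 357), which together covered 693 kb of the mm10 assembly. The fold enrichment of a peak over its local input background, the authors' own value throughout and taken from the authors' deposited table, had a median of 3.66 (interquartile range 3.19 to 4.20) and a range of 1.49 to 8.25. It was 5 or more in 146 peaks, or 6.72%. The highest value lay at Zfp316, a zinc finger gene, on chromosome 5 from 143252937 to 143254835, with a fold enrichment of 8.25 and a summit in a coding exon 2586 bp downstream of the nearest transcription start site (TSS). Fam171a1 followed with 7.40, on chromosome 2 from 3118592 to 3118866, with the summit in an untranslated region 18 bp past an annotated TSS of the gene. The next was a peak over the coding exon of Igkc, the constant region of the immunoglobulin kappa light chain, on chromosome 6 from 70726298 to 70726850, with a fold enrichment of 7.35 and a pileup of 46 fragments. Slc44a1, which encodes a choline transporter, had a summit 370 bp upstream of its TSS and a fold enrichment of 7.09. Snap25, which encodes a synaptic vesicle fusion protein, had one in an intron 924 bp past a TSS at 7.03. The others of the 10 highest lay at Gm10524, whose peak also lay near the TSS of Zfp236 (6.76), Gm2694 (6.54), Ptgfrn (6.51), Vps4a (6.49) and Snhg20 (6.45). The median pileup at the summit was 24 fragments (interquartile range 20 to 28).

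The peaks lay mainly at gene starts. Of the 2173 summits, 1816, or 83.6% (95% exact binomial interval 81.9 to 85.1), lay within 3000 bp of an annotated TSS. Intervals of the same widths placed at random on the same chromosomes gave 16.4% on average, and at most 18.9% in 1000 placements. Introns beyond these promoter windows held 5.84% of summits against 34.9% by placement, and intergenic sequence held 8.38% against 46.4%. Each of these 3 shares lay outside all placements (two-sided permutation p over placements = 0.002, the smallest that 1000 placements can give). Each summit falls in a single class, so the high promoter share by itself lowers the other shares. The intron and intergenic deficits are therefore not findings separate from it. Exons outside the promoter windows held 48 summits, 2.21% against 2.30% (permutation p = 0.859). The exon share was thus not lowered as the others were, at 0.960 times placement against 0.167 for introns and 0.181 for intergenic sequence. Shares among the summits outside promoters alone were not tested. The exon share was higher than by placement among peaks at or above the median fold enrichment, at 3.49% (permutation p = 0.0200), and with promoters narrowed to 1000 bp, at 4.46% (permutation p = 0.0160). With any overlap of the interval counted it was lower, at 2.44% against 3.71% by placement (permutation p = 0.00200), so the call and its direction depended on the setting. The median distance from summit to TSS was 179 bp (interquartile range 66 to 841), against 15614.5 bp for placed intervals, and 33.7% of summits lay within 100 bp of a TSS. Among the peaks at gene starts were those of the hepatoblast and hepatocyte factor Prox1 (fold enrichment 4.06, summit 162 bp past its nearest TSS), the osteopontin gene Spp1 (3.96, 4 bp upstream of its nearest TSS) and the anti-apoptotic gene Mcl1 (3.90, 146 bp upstream). The median fold enrichment was 4.11 in exons, 3.92 in introns and 3.68 in intergenic sequence against 3.62 at promoters.

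**Figure D1:**
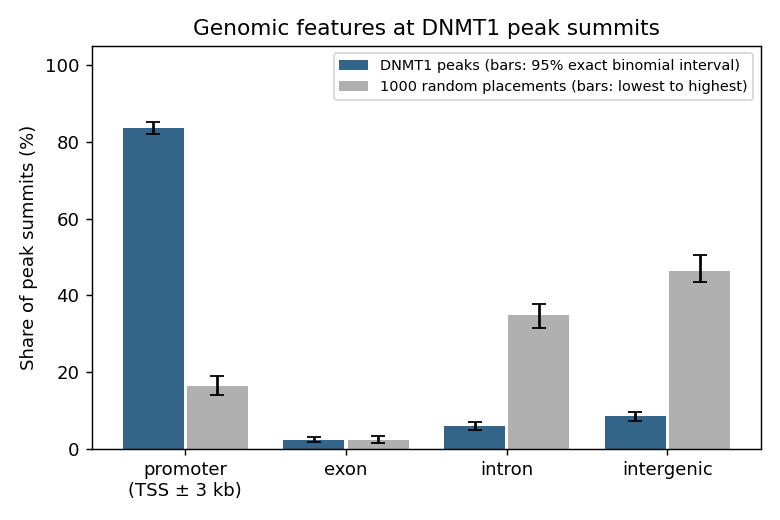
Share of peak summits (%, vertical axis) in promoters (within 3000 bp of a TSS), other exons, introns and intergenic sequence, for the 2173 DNMT1 peaks (blue, error bars 95% exact binomial intervals) and for 1000 random placements (grey, error bars from the lowest to the highest placement). Promoters hold 83.6% of summits against 16.4% by placement, while introns and intergenic sequence hold less than by placement.

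The sequences under the peaks were rich in CpG, the dinucleotide that DNMT1 methylates. Their median GC content was 65.5%, against 41.9% for placed intervals, and the median ratio of observed to expected CpG was 0.806 against 0.152 (both permutation p = 0.002, the smallest possible). A GC content of at least 50% with a CpG ratio of at least 0.6, as in CpG islands, was met by 1566 peaks, or 72.1% (95% exact binomial interval 70.1 to 73.9), against 0.880% of placed intervals. The share was 82.0% among promoter peaks, 52.1% in exons, 22.5% in intergenic sequence and 7.87% in introns. Around the summit there was a median of 8.5 CpG per 100 bp, against 1 in windows 2000 bp to either side. Repeat-masked sequence made up 5.97% of the peaks on average, against 33.5% by placement. Of 21911 protein-coding genes, 1896, or 8.65%, had a summit within 3000 bp of a TSS. The share rose with the CpG ratio of the promoter, from 0.547% (0.283 to 0.954) of genes in the lowest decile to 20.4% (18.8 to 22.2) in the highest. The median promoter CpG ratio was 0.780 in genes with a peak and 0.507 in genes without. The local background that the authors took from the input also stood above its genome-wide level of 2.51 fragments at 97.2% of the peaks, with a median of 2.41 times that level. That background is the highest of several local estimates and the genome-wide level is its lower limit.

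**Figure D2:**
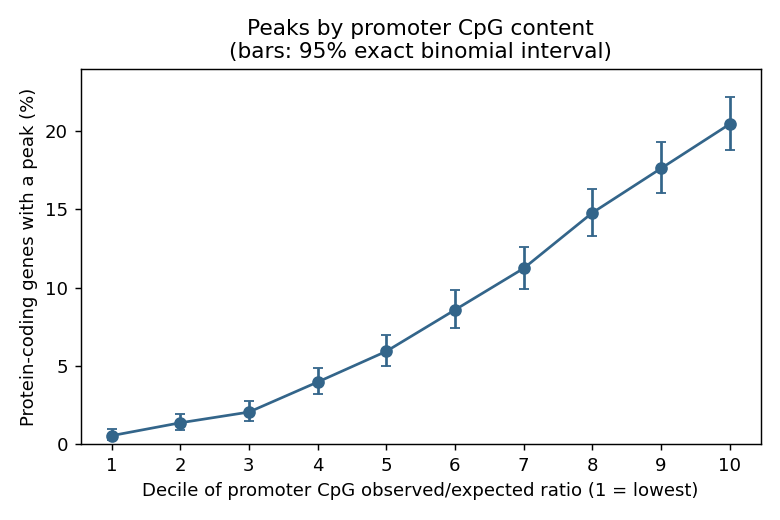
Share of protein-coding genes with a DNMT1 peak summit within 3000 bp of a TSS (%, vertical axis) in 10 equal groups of genes ordered by the CpG observed/expected ratio of the promoter (horizontal axis), with 95% exact binomial intervals. The share rises from 0.547% in the lowest group to 20.4% in the highest.

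The study's title raises the question of whether DNMT1 lay at genes of the Notch and YAP/TEAD pathways and of bile duct cells. Of 43 Notch pathway genes, 6 had a peak, or 14.0%, with an odds ratio of 1.71 (95% interval 0.591 to 4.10, adjusted exact p = 0.481). They were Spen (fold enrichment 5.49), Dll3 (5.14), the receptor gene Notch2 (4.25, 33 bp upstream of the TSS on chromosome 3 from 98013344 to 98013673), Numb (4.18), the ligand gene Jag1 (3.84) and the target gene Hey1 (3.49). The Spen summit with this value lay in a coding exon, 561 bp upstream of a TSS inside the gene. That of Dll3 lay in an intron 2889 bp past its nearest TSS. Within 1000 bp of a TSS, 5 of the 43 Notch pathway genes had a peak. Of 44 YAP/TEAD and Hippo genes, 5 had a peak (odds ratio 1.35, 0.416 to 3.44, adjusted exact p = 0.625). These were Tead1 (4.16, in an intron on chromosome 7 from 112679888 to 112680119), Fat1 (3.93), Mob1b (3.80), Stk4 (3.65) and Dock5 (3.15). Of 30 biliary genes, 5 had a peak (odds ratio 2.11, 0.631 to 5.63, adjusted exact p = 0.481). These were Cd24a (4.79), Cldn7 (4.44), Spp1 (3.96), Sox4 (3.32) and Sox9, a biliary transcription factor gene (2.87, in an untranslated region 106 bp past the TSS on chromosome 11 from 112782204 to 112782602). None of these 3 lists passed the test, and none passed against random lists matched on promoter CpG ratio. The matched lists had a mean of 5.67 genes with a peak for Notch, 5.57 for YAP/TEAD and Hippo and 2.43 for biliary genes. The Notch and YAP/TEAD counts of 6 and 5 were thus close to those of genes with like promoter CpG content. No peak was called within 3000 bp of a TSS of Yap1, Tead2, Tead3, Tead4, Notch1, Dnmt1 itself, or the hepatocyte factor genes Hnf4a and Cebpa. The summits nearest to an annotated TSS of Dnmt1 and of Tead3 lay outside these genes, beyond their 3′ ends and 20550 and 6789 bp downstream of the closest of their TSSs. That nearest to Hnf4a lay 34176 bp upstream.

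Of the 19 gene lists fixed in advance, 3 held a peak more often than other protein-coding genes and 1 less often (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over the lists). Ribosomal protein genes had a peak at 20 of 83 members, or 24.1% (odds ratio 3.38, 95% interval 1.93 to 5.67, adjusted exact p = 0.00019), including Rpl23a (fold enrichment 4.79), Rpl39 (4.67), Rps10 (4.27), Rpl23 (4.09), Rpsa (3.80), Rps18 (3.78), Rpl5 (3.60) and Rpl9 (3.60). Some counted summits lay beyond the 3′ end of the gene, such as that of Rps18, 1299 bp downstream of its nearest TSS. Within 1000 bp of a TSS, 17 of 83 members still had a peak (odds ratio 3.01, adjusted exact p = 0.00221). Immediate early and stress genes had one at 7 of 22 (odds ratio 4.94, 1.70 to 12.9, adjusted exact p = 0.0121), namely Hsp90ab1 (4.28), Hspa8 (4.0), Zfp36 (3.90), Gadd45g (3.35), Ier3 (3.04), Ier2 (2.97) and Jund (2.90). Imprinted genes, which are expressed from the copy of a single parent, had one at 10 of 46 protein-coding members (odds ratio 2.94, 1.30 to 6.06, adjusted exact p = 0.0247). Their 8 distinct peaks lay at Igf2r (5.66), Grb10 (5.64), Rasgrf1 (5.54), Zrsr1 with Commd1 (4.80), Gnas (3.53), Impact (3.33), Peg3 with Usp29 (2.69) and Cdkn1c (2.58). With genes that share a peak counted once, the imprinted list no longer passed (8 of 44, odds ratio 2.35, 0.944 to 5.16, adjusted exact p = 0.245), and neither did it with peaks within 1000 bp (8 of 46, odds ratio 2.45, adjusted exact p = 0.126). Against random lists matched on promoter CpG ratio all 3 calls ended, with adjusted permutation p of 0.118 for ribosomal protein genes and 0.0997 for each of the other lists. Their counts were still 1.64 times the matched mean for ribosomal protein, 2.69 for immediate early and 2.31 for imprinted genes (unadjusted permutation p of 0.0310, 0.0210 and 0.0176), so the lost calls do not show that CpG content accounts for the excess. Among peaks at or above the median fold enrichment the calls also ended, with odds ratios of 1.79 for ribosomal protein, 3.62 for immediate early and 2.80 for imprinted genes. Among peaks with −log10 q of at least 5 all 3 held (odds ratios 3.16, 7.61 and 5.15, adjusted exact p of 0.0452, 0.0202 and 0.0177). Olfactory receptor genes, which are expressed mainly in olfactory neurons, had no peak at any of 1134 members (upper limit 0.325%, adjusted exact p = 6.81e-45). Random lists matched on promoter CpG ratio, with genes drawn independently, had a mean of 12.2 (6 to 19, adjusted permutation p = 0.0038). These genes lie in clusters, and Fisher's exact test called the list in 3 of 20 simulated sets without an effect.

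The other lists did not pass. Tumour suppressor genes had a peak at 8 of 48 (odds ratio 2.12, 0.854 to 4.59, adjusted exact p = 0.247), including Arid2 (4.12), Socs1 (3.90), Dlc1 (3.64), Keap1 (3.57), Cdkn1b (3.38), Rassf5 (3.25) and Cdkn1a (2.86). Cholangiocarcinoma oncogenes had one at 4 of 26 (adjusted exact p = 0.481), which were Fgfr1 (4.87), Idh2 (4.25), Mcl1 (3.90) and Nras (3.08). Genes of the DNA methylation machinery had one at 3 of 30 (adjusted exact p = 0.863), which were Zbtb38 (3.96), Ehmt2 (3.85) and the demethylating enzyme gene Tet3 (3.08). Prox1 was the single member with a peak among 41 hepatocyte genes (odds ratio 0.264, 0.00651 to 1.56, adjusted exact p = 0.481), and Gata4 (3.93) the single one among 20 endothelial genes (adjusted exact p = 1). Markers of stellate cells and fibroblasts (0 of 20, which allows up to 16.8%, adjusted exact p = 0.625), immune cells (0 of 24, up to 14.2%, adjusted exact p = 0.481) and erythroid cells (0 of 11, up to 28.5%, adjusted exact p = 0.834) had none. Hox genes had a peak at 2 of 39 (adjusted exact p = 0.863), Hoxb4 (4.36) and Hoxd9 (4.35), and cell cycle genes at 2 of 30 (adjusted exact p = 1), Mcm7 (4.35) and Mcm4 (2.35). Histone genes had one at 2 of 68 (adjusted exact p = 0.398), Hist3h2a (3.29) and Hist2h4 (3.07), and were below random lists matched on promoter CpG ratio, whose mean was 11.8 (adjusted permutation p = 0.0038). Those lists drew genes independently, whereas histone genes lie in clusters. Fisher's exact test called this list in 5 of 20 simulated sets without an effect, and the matched comparison was not simulated. Zinc finger genes named Zfp with a number had one at 29 of 365 (adjusted exact p = 0.863), with Zfp316, Zfp236, Zfp800 (5.77), Zfp619 (5.23), Zfp560 (5.04), Zfp865 (4.87), Zfp746 (4.85) and Zfp428 (4.55) the highest.

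**Figure D3:**
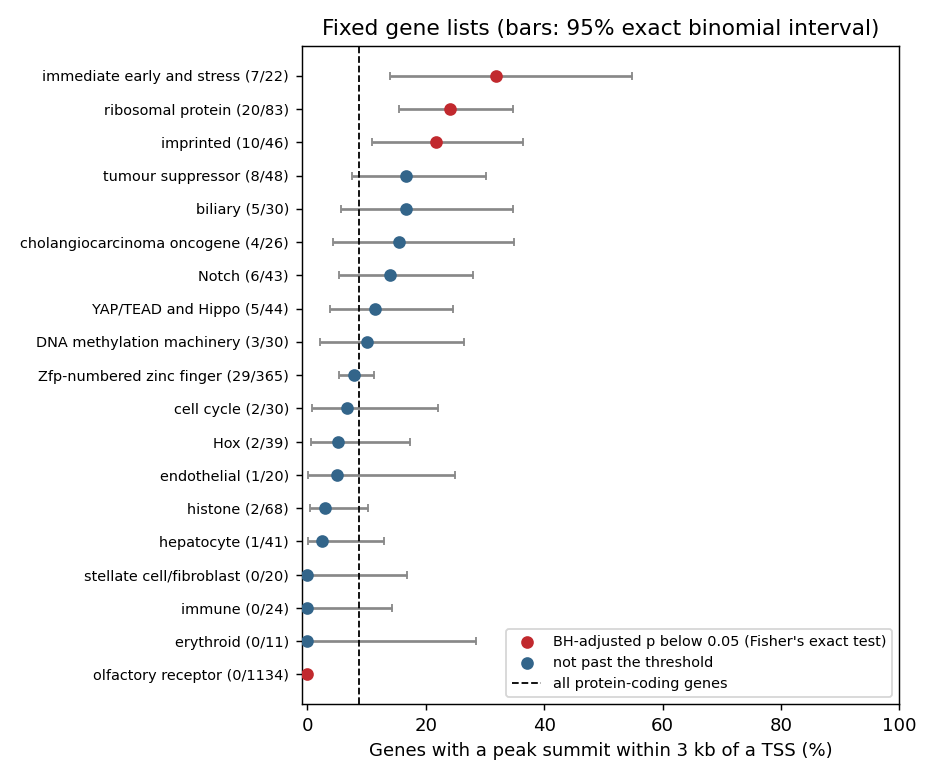
Share of genes with a DNMT1 peak summit within 3000 bp of a TSS (%, horizontal axis) in each of the 19 fixed gene lists, with 95% exact binomial intervals and the numbers of genes with a peak over genes tested. Red points are lists with an adjusted p below 0.05 by Fisher's exact test, blue points are the other lists, and the dashed line marks the 8.65% of all protein-coding genes.

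The binding words of transcription factors were counted in 200 bp around each summit and in windows 2000 bp to either side. The words of 3 promoter and insulator factors were more frequent at the summits. The ETS word CCGGAAGT was present at 2.49% of summits against 0.230% and 0.184% in the flanks, the CTCF word at 1.56% against 0.184% and 0.138%, and the NRF1 word at 0.782% against 0 in both (exact McNemar tests, two-sided, larger adjusted p of both sides 1.05e-10, 2.21e-06 and 3.36e-05). The words of TEAD and of the Notch pathway factor RBPJ were less frequent. TEAD's GGAATG was present at 6.58% of summits against 10.1% and 9.07% (adjusted exact p = 7.99e-05 and 0.00476), and RBPJ's TGGGAA at 14.0% against 19.2% and 19% (larger adjusted exact p = 1.99e-05). The words of the liver factors FOXA (1.1% against 2.25% and 2.76%, larger adjusted exact p = 0.00727) and CEBP in its relaxed form (6.72% against 16.7% and 15.1%, larger adjusted exact p = 2.13e-18) were also less frequent. The words of HNF4A (larger adjusted exact p = 1), HNF1 (1), AP-1 (0.283) and CEBP in its strict form (0.0859) did not pass. FOXA did not pass among peaks at or above the median fold enrichment (adjusted exact p = 0.197), and in 500-bp windows AP-1 passed as less frequent (0.00524) and strict CEBP as more frequent (0.0143). Set against rearrangements of the same bases with as many CpG, a control chosen after the result was seen, the TEAD ratio of 0.691 between summit and flanks lay at percentile 39.0 of its 59 rearranged words and that of RBPJ at percentile 52.5. FOXA and relaxed CEBP lay at percentiles 84 and 96 of their 100, so they were less reduced than most words of the same bases. ETS, CTCF and NRF1 lay above all 100 of theirs (permutation p = 0.0198, the smallest possible, adjusted p = 0.0726). With so few rearrangements and 3 words at that limit, no word could have passed after adjustment, and this control settles nothing for ETS, CTCF and NRF1.

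Peaks were unevenly spread over the chromosomes. The genome held 0.821 peaks per Mb of assembled sequence, and 11 of the 21 chromosomes departed from it (exact binomial tests, two-sided, Benjamini-Hochberg adjusted), with 6 above and 5 below. Chromosome 11 was the densest, with 187 peaks or 1.57 per Mb (95% exact Poisson interval 1.36 to 1.82, adjusted exact p = 7.78e-16). Chromosome X had 38 peaks or 0.232 per Mb (0.164 to 0.319, adjusted exact p = 2.02e-22) and chromosome Y had 2 (adjusted exact p = 1.71e-27). Counted per CpG-rich promoter, chromosome 11 did not stand above the autosomes. There, 14.4% of 842 protein-coding genes with a CpG-rich promoter had a peak (12.1 to 16.9), against 15.2% of 9803 on all autosomes. On chromosome X, 9.38% of 256 such genes had a peak (6.10 to 13.6). Chromosome Y had only 6 such genes, of which 0 had a peak (0 to 45.9%), too few to compare with the autosomes. One of the X-linked genes with a peak was Rpl39, with a fold enrichment of 4.67.

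**Figure D4:**
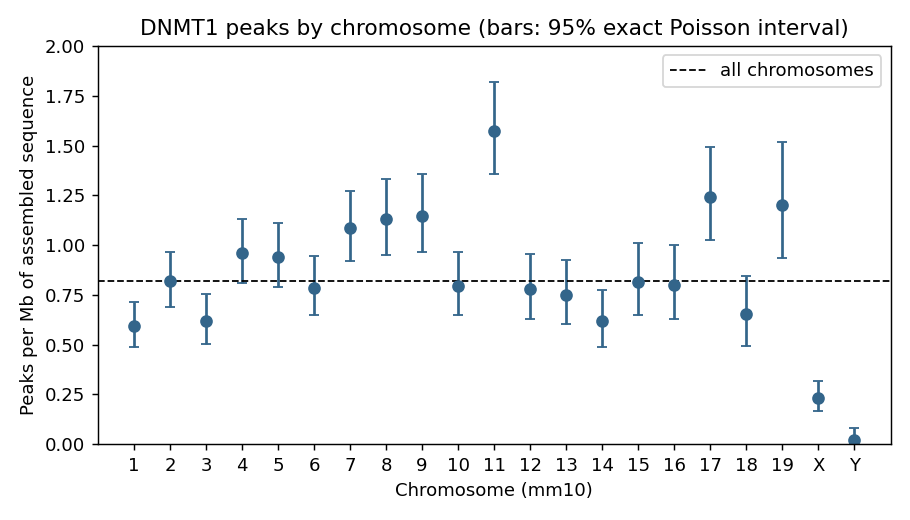
DNMT1 peaks per Mb of assembled sequence (vertical axis) on each mouse chromosome of the mm10 assembly (horizontal axis), with 95% exact Poisson intervals; the dashed line marks the 0.821 peaks per Mb of all chromosomes together. Chromosome 11 stands highest at 1.57 and chromosomes X and Y lowest.

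The peaks with the most fragments had low enrichment. A pileup of at least 100 fragments was reached at 11 peaks, and their fold enrichment ranged from 1.49 to 2.87 with a median of 1.69, against a median of 3.66 and a minimum of 2.15 in the other 2162. The list holds only peaks past the cutoff, and a low fold enrichment passes its Poisson test more readily at a high pileup. Part of this contrast, such as the higher minimum in the other peaks, therefore follows from the cutoff. The cutoff sets no upper limit on the fold enrichment at a high pileup. The highest pileups, 412 and 377, lay on chromosome 17 from 39843065 to 39846720 and from 39847567 to 39848868, beside Gm26917 and over an annotated ribosomal RNA gene. Others lay at Gm10800 (pileup 228, fold enrichment 1.52) and Gm10801 (212, 1.49) on chromosome 2, in an intron of Cdk8 (160, 1.95) and at the TSS of Sfi1 (122, 2.87). The input background at these 11 peaks was 16.6 to 90.6 times its genome-wide level.

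**Figure D5:**
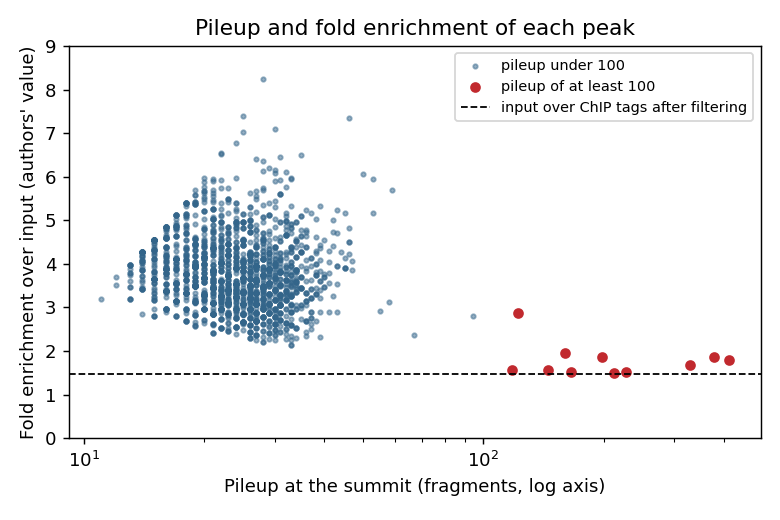
Fragments at the summit of each peak (horizontal axis, log scale) against its fold enrichment over input (vertical axis, the authors' value), for the 11 peaks with a pileup of at least 100 (red) and the other 2162 (blue). The dashed line is the ratio of input to ChIP tags after filtering, 1.48, and the red points lie from 1.49 to 2.87.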

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

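The sets without peaks of a pileup of at least 100, the rearranged words and the imprinted genes counted once per peak were chosen after seeing the data, and the other alternatives were planned. The promoter share (76.6% to 91.1%), GC content, CpG ratio and the departures of chromosomes 11, X and Y kept their direction and their side of the threshold under each alternative run. Peaks at or above the median fold enrichment numbered 1088 with a median fold of 4.20 by construction. In that set 6 chromosomes departed instead of 11, 0 lists were higher instead of 3, and the exon share reversed to 3.49%. Peaks with a −log10 q of at least 5 numbered 641, with a median fold of 4.32, a median width of 310 bp and 4 departing chromosomes. With promoters of 1000 bp the exon share reversed to 4.46%. The cause of these changes was not tested. CpG-matched lists left 0 lists higher and 2 lower. Rearranged words left 0 words higher and 0 lower, but 3 words were at the smallest possible p of 0.0198. None of those could pass after adjustment, so the count of higher words decides nothing. The words called lower were away from that limit, with permutation p of 0.8 for TEAD, 0.967 for RBPJ, 0.337 for FOXA and 0.0990 for relaxed CEBP. For them this control gave no sign of a stronger reduction than in words of the same bases. Across alternatives the adjusted p ranged from 0.000183 to 0.344 for ribosomal protein, 0.00720 to 0.296 for immediate early and 0.00717 to 0.268 for imprinted genes. Among tested values of single lists, words, chromosomes and features, 146 planned and 25 added ones kept their side of the threshold, 8 planned and 1 added one fell short of it and 6 planned ones newly passed it, 2 of them exon shares whose direction reversed. Of the 79 named genes with a peak, 54 kept one at or above the median fold enrichment and 43 at a −log10 q of at least 5. No paired analysis was possible because there was 1 ChIP library and 1 input library. The lowest pileup at a summit in the list was 11 fragments, and how sequencing depth shaped the list was not tested.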

Other observations

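The test of the tag limit, the ratio within bins of GC content, the test of summit position and the count of divergent pairs once were chosen only after the result they address was seen. Near gene starts, summits lay mostly past the outermost annotated start of the gene. Among 1259 protein-coding genes outside divergent pairs with 1 summit within 1000 bp of the start of the gene, the summit lay downstream in 862, or 68.5% (95% exact binomial interval 65.8 to 71.0, exact binomial test p = 5.75e-40). The median offset was 109 bp past the start (interquartile range −70.5 to 270). Other TSSs of a gene can lie inside it, so a summit past the outermost start can still lie upstream of its nearest TSS. Position relative to the nearest TSS was not tested.

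Divergent promoters, where a pair of protein-coding genes start back to back within 1000 bp, held peaks more often than other CpG-rich promoters. Of 1238 such genes 17.9% had a peak, against 14.6% of 8827 others (odds ratio 1.27, 95% interval 1.08 to 1.49, Fisher's exact test p = 0.00296). With each pair counted once and a window of 1000 bp around a single start, the shares were 17.0% of 622 and 12.8% of 8827 (odds ratio 1.40, 1.12 to 1.75, Fisher's exact test p = 0.0031). Double counting alone is therefore unlikely to account for the difference, which remains a hypothesis from this pair of libraries. Each window at a pair still holds the starts of both genes, so a higher chance of a summit from both starts was not excluded.

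A preference for CpG-rich promoters may reflect DNMT1 binding, GC bias of the libraries or recovery of open chromatin whatever is bound there. CpG-rich windows of 300 bp held a summit in 4.76% of 23259 cases within 1000 bp of a TSS and in 2.48% of 808 cases over 10000 bp away, a ratio of 1.92 (1.24 to 2.97). Within bins of GC content and CpG ratio it was 1.61 (1.04 to 2.49), so GC bias cannot be told apart from a preference for promoters as part of the cause, because the interval spans ratios near 1 and above 2. Among CpG-rich promoters, 25.3% of 75 ribosomal protein genes had a peak against 4% of 25 Hox genes (odds ratio 8.03, 1.14 to 352, Fisher's exact test p = 0.0212), as recovery of open promoters would give. The Hox share rests on 1 gene with a peak. Hox genes also lie in clusters, while the test takes genes as independent. This contrast leaves open chromatin and DNMT1 binding at active promoters both open, and with no control antibody or second group no biological explanation was tested.

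The limit of 1 tag per position may have lowered the fold enrichment of the 11 peaks of high pileup, among them those at ribosomal RNA sequence on chromosome 17. It cannot account for their high pileup, since it only removes tags. With tags extended to fragments on both strands that limit allows a pileup of up to 450, and the 11 peaks reached a median share of 0.440 of it (0.262 to 0.916). The 2 on chromosome 17 with pileups of 412 and 377 were above 0.8 and the other 9 were below. The limit cannot be told apart from low enrichment of these sequences, because the number of positions where tags can be placed in repeated sequence is not known here. Part of the contrast with the other peaks also follows from the cutoff, which a low fold enrichment passes more readily at a high pileup. No biological explanation was tested for this pattern.

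Chromosome X had fewer peaks than the autosomes, and fewer CpG-rich promoters could be one reason. Among CpG-rich promoters the odds ratio of a peak on X over autosomes was still 0.577 (0.361 to 0.883, Fisher's exact test p = 0.00788), which argues against it as the whole cause. The single X of male animals is a candidate explanation that stays open. With pileup and background halved, a share of 0.447 of the autosomal peaks still passed the lowest p-value of the list. That lay inside the interval of 0.420 to 0.905 for the share of CpG-rich promoters with a peak on X relative to autosomes (ratio 0.616). These are unlike measures, a share of all autosomal peaks and a ratio of promoter shares, so the comparison does not decide. The share of 0.447 was not set against the lower number of peaks per Mb on X. Differences in DNMT1 binding on X were not tested.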
